A study of Mus musculus with 8 samples.

How the data were processed

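Liver RNA of C57BL/6 mice at postnatal day 7 was compared between 4 wild-type (WT) and 4 Hmgcs2 knockout (KO) libraries, with each library's genotype and replicate number taken from its title. Per the labels' protocols, messenger RNA was purified by its poly(A) tail, made into libraries with a New England Biolabs kit and sequenced as single-end reads of 75 bases. The protocol text speaks of HEL cells, a human cell line, although the organism and source in the labels are mouse and liver. TopHat and the human build hg19 are named in the submitters' processing notes, without their roles, but the gene names in the table are mouse symbols, so no coordinates are given here. The counting tool, the annotation and whether strand was used are not given in the sources used here. The authors deposited estimated counts per gene, not divided by library size or length, in a single table with a column per library; 89.3% to 90.5% of the values in a column were whole numbers, to within 1e-9. Fractional values may come from reads divided between features, which was not tested, and genes named here with fractional values in 6 or more libraries are reported as uncertain.

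The table held 24411 gene names. Against a mouse gene table of RefSeq, 23605 names matched as symbols and 684 as synonyms, 27 had the form of a date, as spreadsheet programs make from some symbols, and 95 did not match. Names were used as deposited. Mitochondrial-genome transcripts were not analysed here. Total counts per library ran from 13383821 to 19558904, and WT libraries were deeper than KO libraries except WT 4. Replicates of a genotype differed by more than counting noise, with a mean chi-square per gene of 6.06 to 27.1 between pairs. The median over genes was lower, at 1.05 to 2.65. No library was counted as a repeat of another, although these values cannot show that the libraries came from separate animals.

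Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 13424 genes. Libraries were scaled with TMM factors, and genotype was tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes kept, at an adjusted p threshold of 0.05. All 8 libraries entered the fit, with genotype as the only term, since the labels name no batch, litter, date or sex. The biological coefficient of variation was 11.7%. Standard errors of log2 fold changes were computed as the size of the log2 fold change divided by the square root of the F statistic. Each gene described as higher, lower, risen or fallen passed this test, and values are TMM-normalised counts in CPM. Principal components and list scores used log2 CPM with a prior count of 2.

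The tests, the gene lists and the rule for naming genes were fixed before the data were examined. Of 45 gene lists, 41 were tested with camera (limma 3.58.1) on voom values with its preset inter-gene correlation of 0.01, adjusted over the 41 lists, and again with a correlation estimated from the data. The lists not tested were mitochondrial-genome transcripts, the pancreas and the adipose, mesothelium and muscle lists, which had fewer than 5 tested members, and sex-linked genes, used as a check of the animals. Members that changed were counted with the adjustment over all genes and again over the members of the list alone. Some genes belong to several lists.

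Named genes were Hmgcs2, then the 10 changed genes with the largest log2 fold change in each direction among those with a mean of at least 5 CPM in a genotype, the 5 with the smallest p in each direction, and up to 4 members with the smallest p per list, leaving out predicted genes and pseudogenes. The number named per list was later brought down to 3 for lists called and 2 for the others, after values were seen. From the genes near Hmgcs2 and from the lysosomal, pericentral and periportal lists, the genes to name were chosen after their values were seen. How the lysosomal and pericentral lists were written is given with their results.

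The fit was tested on simulated counts drawn from the real means and library sizes, with 100 genes moved by a log2 fold of 0.5, 100 by 1 and a list of 25 by 0.4. Of these, 71%, 95% and 11 of the 25 were recovered among 13351 genes tested, and 10 of 187 calls (5.35%) were false. An unmoved list had a camera p of 0.742, but the simulated genes were drawn independently of each other. The simulation therefore does not test camera on lists whose members are correlated. It also moved far fewer genes than the 2783 called in the data, and gave genes of similar mean a similar spread. The recovered and false shares need not hold for the real fit. The alternatives fixed in advance were DESeq2 size factors, upper-quartile scaling, library size alone, no filter on low counts, a filter of 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, replicate number as a block, 1 surrogate variable (sva 3.50.0), the Y-linked level as a covariate (log2 CPM with 0.5 added), erythroid genes left out, each library left out, an estimated correlation, and list members held in 1 list only. Added after seeing the data were thinning to the smallest library, the libraries with and without Y-linked reads apart, genes with at least 1% of counts left out, a length and GC trend removed, and the libraries without WT 1 and WT 4. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.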

Results

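Polyadenylated RNA was measured in liver of C57BL/6 mice at postnatal day 7, an age at which pups live on fat-rich milk. The 8 libraries fell into 2 genotypes, 4 wild type (WT) and 4 knockout (KO) for Hmgcs2. This gene encodes the mitochondrial 3-hydroxy-3-methylglutaryl-CoA synthase, the rate-limiting enzyme of ketone body synthesis. Total estimated counts per library were 19066630, 19558904, 18715843 and 14514276 in WT 1 to WT 4, and 14464041, 14586807, 13977662 and 13383821 in KO 1 to KO 4. The labels do not say whether each library came from a separate animal, so every p-value measures only the spread between these libraries. Values below are the mean ± SD of TMM-normalised counts in CPM over n = 4 libraries per genotype, or the log2 fold change of KO over WT ± its standard error.

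The design asks which liver transcripts differ when Hmgcs2 is disrupted. Hmgcs2 itself fell from 2799.6 ± 429.6 CPM in WT to 94.0 ± 8.21 CPM in KO. Its counts were 48596, 47122, 58288 and 38774 in the WT libraries and 1269, 1452, 1314 and 1456 in the KO libraries, so each library matched its label. The log2 fold change was -4.90 ± 0.13, a 29.8-fold difference, with an adjusted p of 2.58e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Which part of the transcript gave the remaining KO counts was not analysed here.

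**Figure D1:**
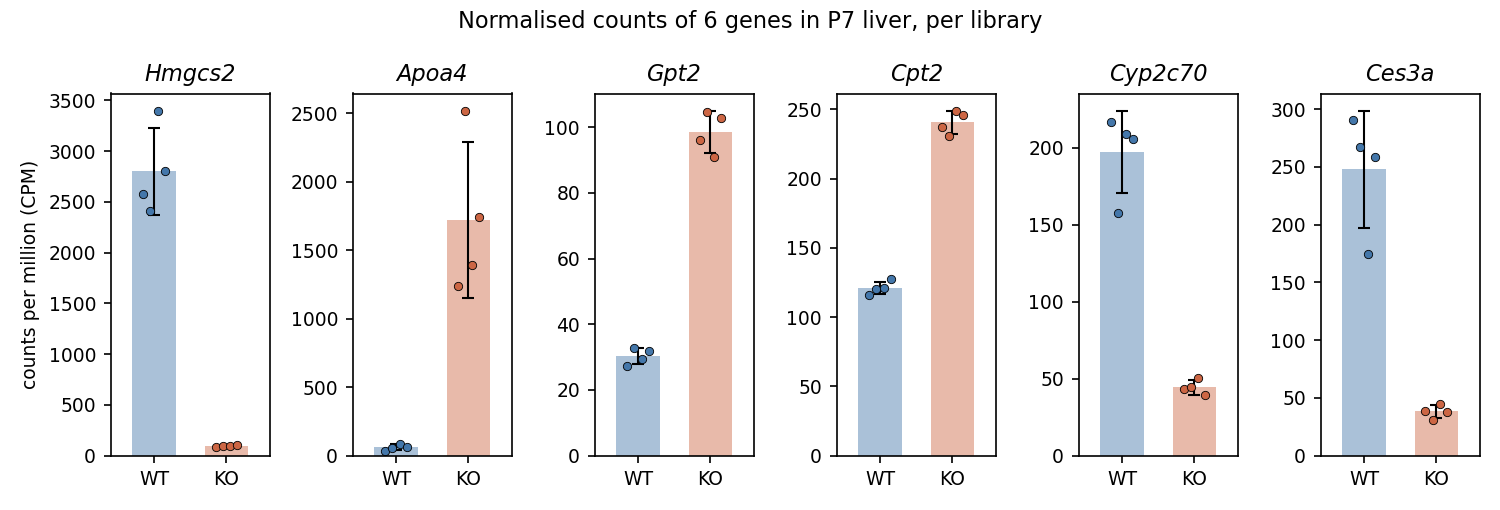
Normalised counts in CPM (y axis, linear and starting at 0) of 6 genes in WT and KO liver. Bars are means, error bars are SDs and points are the 4 libraries of each genotype; Hmgcs2, Cyp2c70 and Ces3a lay lower, and Apoa4, Gpt2 and Cpt2 higher, in every KO library than in any WT library.

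Across the liver transcriptome, 18 of 24 tested genes of mitochondrial fatty acid oxidation and 33 of 70 of the respiratory chain rose in KO, and 10 of 15 hepatocyte markers and 11 of 18 lymphocyte markers fell. As lists, however, none was called when the correlation between genes was estimated. Of 13424 genes tested, 2783 changed at an adjusted p under 0.05, with 1597 higher and 1186 lower in KO. At least a 2-fold difference was seen in 171 of the higher and 194 of the lower genes. In 2472 of the changed genes (88.8%) all 4 KO libraries lay on the same side of all 4 WT libraries. Since these genes were called on the same libraries, this share is no separate support for the calls. The first principal component held 46.5% of the variance and ran from -30.3 to -18.8 in WT and from 20.1 to 27.6 in KO. The share of calls that were higher depended on the scaling: it was 57.4% with TMM factors, 42.8% (1212 higher, 1620 lower) with upper-quartile scaling and 79.9% (2783 higher, 701 lower) with library size alone.

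Among genes with a mean of at least 5 CPM in a genotype, several of the largest rises were in lipid handling. Apoa4, an apolipoprotein of triglyceride-rich particles, rose from 59.8 ± 21.8 to 1722 ± 571 CPM (log2 fold change 4.85 ± 0.31). Cidec, a lipid droplet protein, rose by 3.82 ± 0.34, Acot1, an acyl-CoA thioesterase, by 3.27 ± 0.22, and Cyp4a12a, a fatty acid hydroxylase, by 4.92 ± 0.45. Cpt1b, the muscle form of carnitine palmitoyltransferase 1, rose by 4.01 ± 0.63, although WT 2 and WT 4 held no counts and the DESeq2 test did not call it. The water and glycerol channel Aqp3 (3.12 ± 0.43), the giant sarcomere gene Obscn (3.55 ± 0.24), the glutathione transferase Gsta2 (2.70 ± 0.20), the ubiquitin-like gene Ubd (3.03 ± 0.72) and Tgoln2 (3.32 ± 0.89) completed the 10 largest rises. KO 4 held 59.3 CPM of Ubd against 5.42 to 13.3 CPM in the other KO libraries. Limma-voom did not call Ubd, with or without quality weights (2.07 and 2.40). Tgoln2 was no longer called by DESeq2 (3.45) or without KO 2 (3.26) or KO 4 (2.96), and neither gene with the Y-linked level as a covariate (Ubd 2.39, Tgoln2 2.83). The smallest p-values among higher genes belonged to Gpt2, the mitochondrial alanine aminotransferase (from 30.3 ± 2.42 to 98.6 ± 6.38 CPM), Srxn1 (1.40 ± 0.075), the bile acid conjugating enzyme Baat (1.67 ± 0.097), Cpt2 (0.99 ± 0.059) and Baiap2l1 (1.23 ± 0.073).

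Besides Hmgcs2, the largest falls were in Hamp, the iron hormone hepcidin (-4.13 ± 0.77), the protease inhibitor Serpina3k (-3.39 ± 0.49), the pancreatic lipase relative Pnliprp1 (-3.35 ± 0.21) and the organic anion transporter Slc22a7 (-3.07 ± 0.37). Cyp2c54 (-2.82 ± 0.14), Sult2a6 (-2.72 ± 0.14) and Ces3a (-2.69 ± 0.16), which act on drugs, steroids and esters, fell as well, as did Cyp2c50 (-1.86 ± 0.087) and Cyp2c70 (-2.15 ± 0.11). The mucin Muc1 fell by 2.93 and the smooth muscle actin Actg2 by 2.41, but without WT 1 and WT 4 the values were -0.59 and -0.22 and neither was called, nor was either by limma-voom (-2.14 and -1.68). Muc1 held 13.01 and 12.5 CPM in WT 1 and WT 4 and 1.95 and 0.758 CPM in WT 2 and WT 3. The Muc1 call ended without WT 1 (-2.41), WT 4 (-2.52), KO 1 (-2.74), KO 2 (-2.77) or KO 4 (-3.01). The Actg2 call ended when any library other than WT 2 or WT 3 was left out (-2.62 to -1.89). Fractional counts in all 8 libraries, whose origin was not tested, were seen for Acot1, Acot2, Acaa1b, Cyp2c50, Cyp2c54, Sult2a6, Serpina3k, Serpina3m, Serpina1a, Serpina1c, Apoc2, Aco2, Ndufs1, Grpel1, Ces1c, Ttr and Hba-a1, in 7 for Gapdh, Uqcrc2 and Hba-a2, and in 6 for Cyp4a12a, Gsta2, Tgoln2, Dnajb9 and Itih3, so their folds are uncertain.

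Most tested fatty acid oxidation genes were higher in KO in both organelles. In the mitochondrial list, 18 of 24 tested members rose (18 adjusted over the list alone). They included Cpt2, which releases acyl-CoA inside mitochondria (121 ± 4.54 to 241 ± 8.22 CPM), Acot2 (2.43 ± 0.19) and the dienoyl-CoA reductase Decr1 (0.70 ± 0.063). In the peroxisomal list, 13 of 19 rose (14 adjusted over the list alone), among them the bifunctional enzyme Ehhadh (1.71 ± 0.14), the thiolase Acaa1b (1.10 ± 0.099) and the transporter Abcd3 (0.67 ± 0.061). Of the targets of the fatty acid receptor PPARA outside oxidation, 17 of 23 rose (20 higher and 1 lower adjusted over the list alone), led by Acot1, Plin2 (1.17 ± 0.096) and Cidec. By camera the adjusted p was 3.41e-12, 4.73e-08 and 1.60e-12 for these 3 lists. The adjusted p with an estimated correlation was 0.263 for the mitochondrial list and 0.215 for both the peroxisomal list and the PPARA targets.

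Many mitochondrial energy genes rose as well. The citric acid cycle and pyruvate entry list had 19 of 25 members higher (21 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.16e-12), with Suclg1 at 0.68 ± 0.063, Aco2 at 0.76 ± 0.076 and Dlst at 0.61 ± 0.065. Nuclear-encoded respiratory chain and ATP synthase genes had 33 of 70 higher (41 adjusted over the list alone; camera adjusted p = 8.97e-12), such as Ndufs1 (0.56 ± 0.065), Uqcrc2 (0.46 ± 0.058) and Cyc1 (0.58 ± 0.078). Of the mitochondrial chaperones and proteases, 11 of 16 rose (13 adjusted over the list alone; camera adjusted p = 4.73e-08), including Grpel1 (0.50 ± 0.055), Afg3l2 (0.54 ± 0.062) and Lonp1 (0.60 ± 0.069). The list of sirtuins, NAD and acetyl-CoA handling had 9 of 23 higher (15 adjusted over the list alone; camera adjusted p = 1.21e-05), led by the mitochondrial acetyl-CoA synthetase Acss1 (1.34 ± 0.20), the coenzyme A carrier Slc25a42 (0.62 ± 0.094) and carnitine acetyltransferase Crat (0.68 ± 0.10). Adjusted p with an estimated correlation was 0.499 for the respiratory chain and 0.215 for the other 3 lists. Mitochondrial-genome transcripts were not analysed here.

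Some glycolytic enzymes were higher too. In the glycolysis and hypoxia list 10 of 22 members rose (10 adjusted over the list alone; camera adjusted p = 1.13e-04, adjusted p = 0.374 with an estimated correlation). Gapdh rose by 0.84 ± 0.093, Tpi1 by 0.73 ± 0.083 and Pgk1 by 0.60 ± 0.073, all 3 of them enzymes of glycolysis. Genes of glucose production and glycogen went both ways (6 higher and 5 lower of 21; 8 higher and 5 lower adjusted over the list alone): Gpt2 rose, while Ppp1r3b, a glycogen-targeting phosphatase subunit, fell (-1.30 ± 0.14). Urea cycle and nitrogen genes did the same (4 higher and 3 lower of 15; 4 higher and 3 lower adjusted over the list alone), with the aspartate-glutamate carrier Slc25a13 up (0.61 ± 0.062) and Nags down (-0.57 ± 0.071). Camera called neither list (adjusted p = 0.330 and 0.708).

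Some lipid storage genes rose, and lipid synthesis genes had no common direction. Of the lipid droplet and triglyceride turnover genes, 9 rose and 1 fell of 21 (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.38e-04, adjusted p = 0.215 with an estimated correlation). The droplet coat genes Plin3 (1.04 ± 0.075) and Plin2 were among them, with the droplet enzyme Hsd17b13 (0.86 ± 0.077). The lipogenesis list had 6 members higher and 6 lower of 21 (8 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.927), with malic enzyme Me1 at 1.32 ± 0.10 and Mid1ip1 at -0.88 ± 0.076. Lipoprotein genes were also divided (5 higher and 6 lower of 19; 5 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.384), Apoa4 and Apoc2 (1.08 ± 0.089) being the strongest. Cholesterol synthesis was called lower by camera (adjusted p = 0.0467, adjusted p = 0.773 with an estimated correlation), yet only Tm7sf2 (-0.49 ± 0.10) and Ebp (-0.25 ± 0.067) fell and Hsd17b7 rose (0.58 ± 0.15) of 26 members (1 higher and 2 lower adjusted over the list alone). That list call ended without WT 3 (median -0.14), WT 4 (-0.082), KO 1 (-0.20) or KO 4 (-0.092), or both WT 1 and WT 4 (-0.16). With all 8 libraries it ended with the DESeq2 Wald test (-0.20), limma-voom quality weights (-0.16), replicate number as a block (-0.19), 1 surrogate variable (-0.20) and the Y-linked covariate (-0.11). The Ebp call ended with library size alone (-0.14) or the Y-linked covariate (-0.21), and without WT 4 (-0.19) or KO 2 (-0.23), and the Hsd17b7 call without KO 2 (0.47).

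Other ketone body genes than Hmgcs2 changed in both directions. The list of ketone body enzymes and transport, which leaves out Hmgcs2, had 3 members higher and 2 lower of 9 tested (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.848). The monocarboxylate transporter Slc16a7 rose from 43.8 ± 2.87 to 77.5 ± 5.72 CPM. Hmgcl, the lyase that acts directly after Hmgcs2, rose by 0.38 ± 0.065. Without WT 4, KO 1, KO 2, KO 3 or KO 4, and with the Y-linked covariate, the list had 2 members higher and 1 lower. The 2 lower members were Oxct1 and Aacs. With replicate number as a block neither was called (-0.46 and -0.40), and the list had 2 higher and 0 lower.

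Many antioxidant genes rose, while some genes of the secretory stress response fell. Of the targets of NRF2, a regulator of antioxidant defence, 13 rose and 1 fell of 23 (16 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.24e-07, adjusted p = 0.215 with an estimated correlation). Sulfiredoxin Srxn1 went from 26.7 ± 1.33 to 70.4 ± 5.65 CPM, and the carbonyl reductase Cbr3 rose by 2.57 ± 0.18. In the endoplasmic reticulum unfolded protein list, 4 fell and 1 rose of 19 (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.00200, adjusted p = 0.559 with an estimated correlation), with Xbp1 at -0.59 ± 0.057, Herpud1 at -0.53 ± 0.11 and Dnajb9 at 0.32 ± 0.068. ATF4 targets of the integrated stress response had 4 higher and 1 lower of 26 (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.125), including Trib3 (1.83 ± 0.16) and Shmt2 (0.53 ± 0.074), and were called higher as a list without WT 3 (median 0.15). Targets of p53 had 4 higher and 2 lower of 15 (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.267), with Aen at 0.54 ± 0.10 and Gdf15, also an ATF4 target, at 1.19 ± 0.24.

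Many transcripts of secreted liver proteins fell. In the hepatocyte marker list 10 of 15 members fell (10 adjusted over the list alone; camera adjusted p = 2.01e-07, adjusted p = 0.215 with an estimated correlation). The plasma carrier Ttr fell from 9275 ± 849 to 5246 ± 698 CPM, and the antitrypsin genes Serpina1c and Serpina1a by 0.85 and 0.69. Of acute phase proteins, 13 fell and 4 rose of 26 (5 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.559 with an estimated correlation), with fibrinogen Fgb at -0.56 ± 0.076, Itih3 at -0.51 ± 0.066 and Serpina3m at -0.59 ± 0.081. Genes that mark postnatal hepatocyte maturation had 7 lower and 2 higher of 23 (3 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0116, adjusted p = 0.418 with an estimated correlation). Its median was -0.098, but 0.0057 when libraries were scaled by size alone, and the call ended without WT 1 and WT 4 (-0.092). The carboxylesterase Ces3a went from 248 ± 50.8 to 38.4 ± 5.69 CPM, the ethanol-oxidising Cyp2e1 from 3058 ± 105 to 1655 ± 136 CPM and Ces1c fell by 0.94. The fetal liver list had 4 higher and 6 lower of 20 (5 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.559), the lower ones including Dlk1 (-1.42 ± 0.17) and Cdkn1c (-0.56 ± 0.083).

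Drug and bile acid metabolism changed gene by gene. Targets of the xenobiotic receptors CAR and PXR had 6 higher and 8 lower of 22 (8 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.927), Cyp2c50 and Cyp2c54 falling most clearly. Bile acid genes were split evenly at 5 higher and 5 lower of 21 (6 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.761). Baat rose from 20.5 ± 0.286 to 65.1 ± 9.22 CPM and Cyp8b1, the sterol 12-alpha-hydroxylase, from 189 ± 23.8 to 544 ± 59.3 CPM.

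Clock and signalling genes shifted singly. The clock gene Per1 fell from 37.0 ± 7.25 to 11.9 ± 0.985 CPM and Rorc by 1.09, within a clock list of 3 higher and 6 lower of 17 (4 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.164). Glucocorticoid and fasting genes had 4 higher and 5 lower of 18 (7 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.708), with the lipase inhibitor Angptl4 at 1.22 ± 0.13. The growth hormone and IGF axis had 2 higher and 4 lower of 12 (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.120), including the prolactin receptor Prlr (-0.64 ± 0.085). Camera called that list lower with library size alone (median -0.20) and with members held in 1 list only (-0.40). Immediate early and heat shock genes had 2 higher and 4 lower of 18 (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.103), with Ier2 at -1.03 ± 0.072 and Hsp90aa1 at 0.40 ± 0.093, and was called lower with library size alone (median -0.16) and without WT 4 (-0.37). The cell cycle list had a median of 0.16, towards higher, without a camera call (adjusted p = 0.0703), although Ccnd1 fell (-0.87 ± 0.15), 1 of 30 members (1 adjusted over the list alone). Camera called that list higher without WT 2 (0.28), WT 3 (0.19) or KO 4 (0.26), with no filter on low counts (0.16) and with replicate number as a block (0.17). Single members rose too: 2 without WT 2, 5 without KO 4, 3 with library size alone and 4 with the Y-linked covariate, with 1 lower each time.

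**Figure D2:**
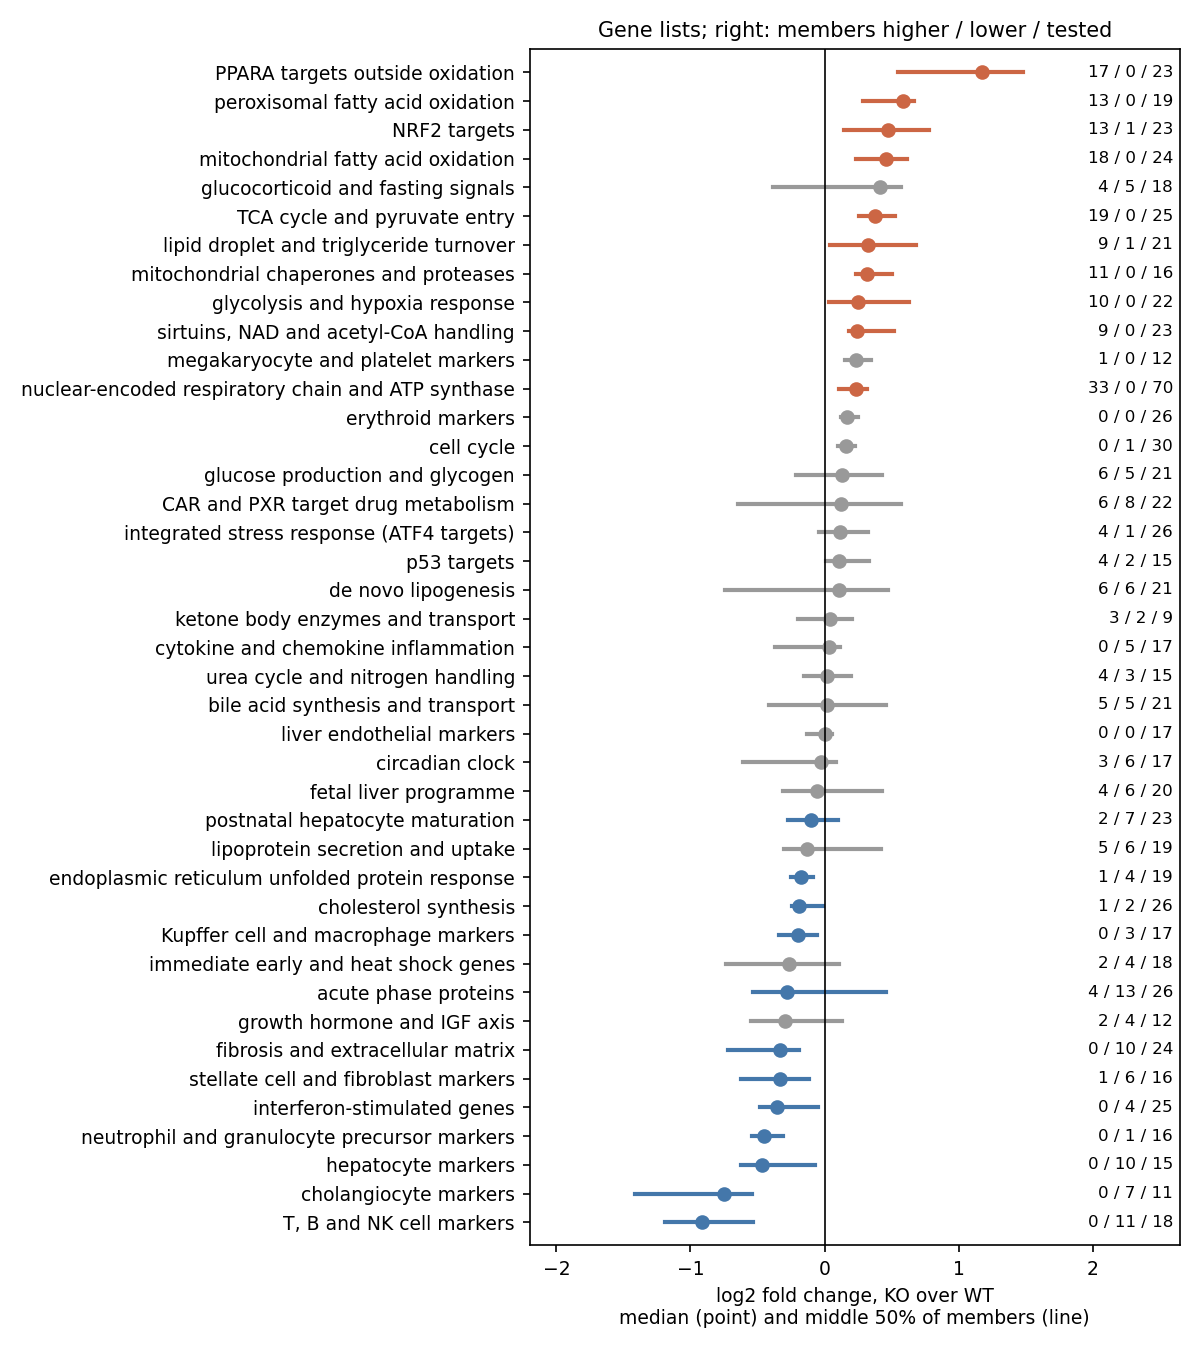
Median log2 fold change of KO over WT (x axis) for the 41 gene lists tested (y axis), as points, with the middle 50% of members as lines; orange and blue mark lists that camera called higher and lower in KO with its preset correlation, grey those not called. The numbers at the right are members higher, lower and tested; fat oxidation, PPARA, NRF2 and citric acid cycle lists lie to the right, and lymphocyte, cholangiocyte and hepatocyte marker lists to the left.

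Many markers of lymphocytes and connective tissue cells were lower in KO. Among T, B and NK cell markers 11 of 18 fell (11 adjusted over the list alone; camera adjusted p = 2.74e-06, adjusted p = 0.215 with an estimated correlation), including the B cell receptor genes Cd79a (10.2 ± 2.88 to 3.35 ± 0.744 CPM) and Cd79b (-1.18 ± 0.18) and the precursor B cell gene Vpreb3 (-1.66 ± 0.29). Stellate cell and fibroblast markers had 6 lower and 1 higher of 16 (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 1.44e-04, adjusted p = 0.215 with an estimated correlation), with Lum at -1.47 ± 0.19, Ecm1 at -0.61 ± 0.084 and Reln at -0.64 ± 0.10. In the fibrosis and matrix list 10 of 24 fell (13 adjusted over the list alone; camera adjusted p = 2.24e-04, adjusted p = 0.418 with an estimated correlation), with Mmp2 at -0.87 ± 0.13, Timp2 at -0.64 ± 0.13 and Mmp14 at -0.36 ± 0.076. Cholangiocyte markers had 7 of 11 lower (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.00263, adjusted p = 0.418 with an estimated correlation), with Spp1 at -0.75 ± 0.14, Epcam at -1.43 ± 0.30 and Sox9 at -0.51 ± 0.12. The mean of the cholangiocyte markers, as a log2 deviation from the mean of all libraries, was 0.89 in WT 1 and 1.01 in WT 4, against -0.29 to 0.091 in WT 2 and WT 3 and -0.53 to -0.24 in KO. Without WT 1 and WT 4, Sox9 (-0.39) and Mmp14 (-0.30) were not called, and 2 cholangiocyte markers and 3 fibrosis genes fell. The fibrosis list was also highest in WT 4 (0.50) and WT 1 (0.27).

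**Figure D3:**
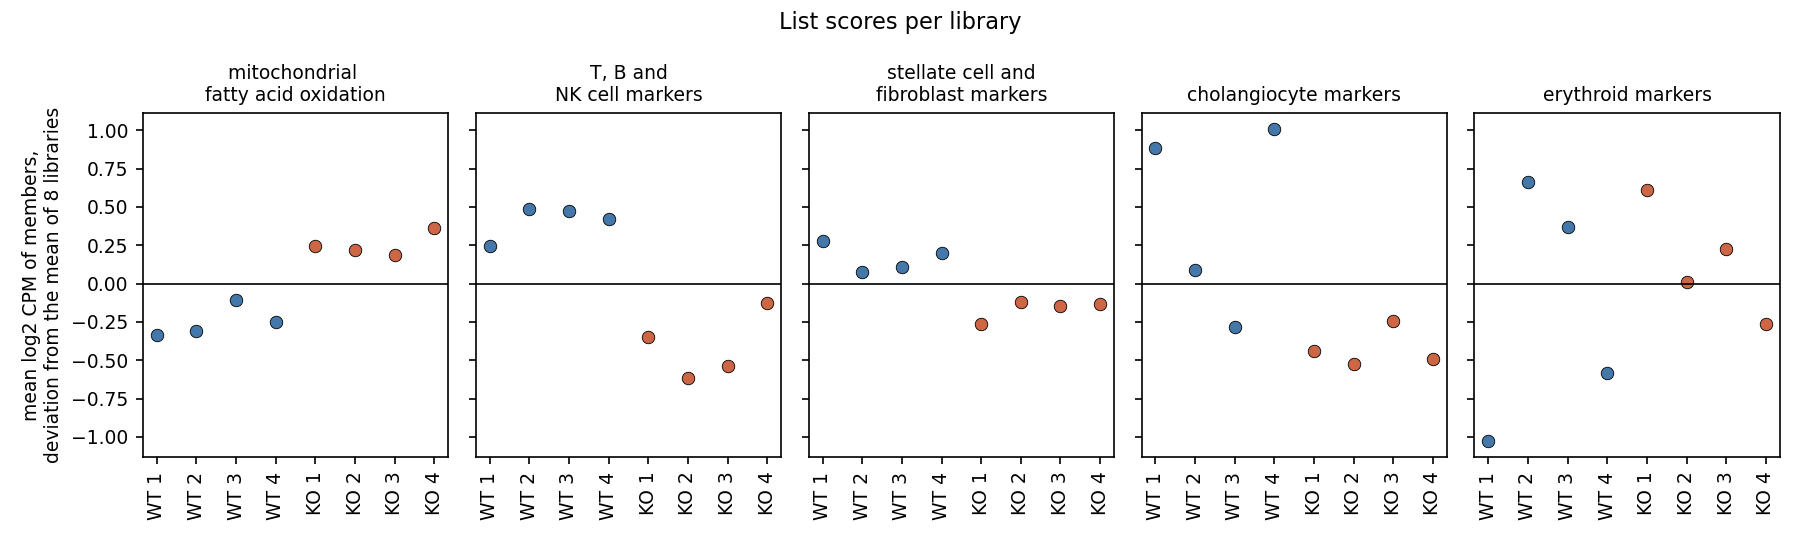
Mean log2 CPM of the members of 5 lists in each library (y axis, as the deviation from the mean of the 8 libraries; x axis, libraries), WT in blue and KO in orange. The oxidation, lymphocyte and stellate lists part the genotypes completely, the cholangiocyte list is high in WT 1 and WT 4 (0.89 and 1.01), and the erythroid list varies within both genotypes.

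With edgeR's test on all 8 libraries and genotype as the only term, fewer members changed in the lists of other blood and liver cell types. The difference between lists was not tested and depended on the libraries used. Without KO 4, for example, 8 Kupffer cell and macrophage markers fell. Kupffer cell and macrophage markers had 3 of 17 lower (3 adjusted over the list alone; camera adjusted p = 0.0116, adjusted p = 0.620 with an estimated correlation), with Clec4f at -0.42 ± 0.064 and Vsig4 at -0.42 ± 0.082, and this list call ended without KO 3 (median -0.12). In the neutrophil list 1 of 16 fell, Chil3 (-0.70 ± 0.18; 1 adjusted over the list alone; camera adjusted p = 0.00631, adjusted p = 0.620 with an estimated correlation). The count was 6 without KO 1, 8 without WT 1, 3 with quality weights and 11 with 1 surrogate variable, and included Ngp (-0.78 without KO 1) and S100a9 (-0.74) each time. Both calls ended without KO 2 (Chil3 -0.63, list median -0.33). The list median of -0.46 came to -0.031 with the Y-linked level as a covariate, and was not called. The mean of the neutrophil markers parted the libraries by Y-linked reads, not by genotype. It was 0.32 to 0.39 in WT 2 to WT 4 and KO 1, which lacked them, and -0.51 to -0.26 in WT 1 and KO 2 to KO 4. Leaving out WT 1 or KO 1 ties genotype more closely to these reads, so the larger counts are no separate support for a fall in KO. Interferon-stimulated genes had 4 of 25 lower (none adjusted over the list alone; camera adjusted p = 0.0116, adjusted p = 0.710 with an estimated correlation), and the list call ended without WT 2 (median -0.17), KO 2 (-0.28) or KO 3 (-0.30), and with the DESeq2 Wald test (-0.36). Of the 25 members, 8 had an unadjusted p under 0.05, and DESeq2 called 4 and limma-voom 5. Leaving out 1 library gave 0 (without KO 1, KO 2 or KO 3) to 7 (without KO 4) lower members, the Y-linked covariate 0 and 1 surrogate variable 8. Oasl2 had the smallest p of the members that fell (-0.78 ± 0.21), and was not called without KO 1 (-0.75), KO 2 (-0.70) or KO 3 (-0.77), or with the Y-linked covariate (-0.74). Inflammatory cytokines and chemokines had 5 of 17 lower (5 adjusted over the list alone; camera adjusted p = 0.0707), including Il1b (8.36 ± 2.54 to 1.95 ± 0.491 CPM) and Vcam1 (-0.37 ± 0.069). Camera did call that list lower without WT 1 (median -0.022), WT 4 (-0.052), KO 4 (-0.21) or both WT 1 and WT 4 (-0.17), with quality weights (-0.16), with no filter on low counts (-0.18) and with library size alone (0.14). In the platelet list only Gp1ba passed (0.47 ± 0.15), 1 of 12 members (none adjusted over the list alone; camera adjusted p = 0.173), with 3 at an unadjusted p under 0.05 and 2 called by DESeq2, and not when WT 1, WT 2, WT 4, KO 1, KO 3 or KO 4 was left out (0.37 to 0.49). The platelet list was called higher without WT 2 (median 0.41).

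Erythroid markers and liver endothelial markers had no changed member, 0 of 26 and 0 of 17 with edgeR's test, with DESeq2 and with limma-voom, and with 0 and 2 members at an unadjusted p under 0.05 (none adjusted over the list alone; camera adjusted p = 0.164 and 0.708). With 1 surrogate variable, however, 2 erythroid members, Ermap (0.21) and Hba-a2 (-0.50), and 2 endothelial members, Lyve1 (-0.41) and Stab2 (0.29), were called. Stab2 was also called with quality weights (0.28), with library size alone (0.35) and without WT 1 (0.36), and without both WT 1 and WT 4 Hba-a2 (-0.85), Lyve1 (-0.55) and Stab2 (0.31) were. The erythroid list (median 0.17) was called higher without WT 2 (0.50), WT 3 (0.31) or KO 4 (0.30), but lower without WT 1 and WT 4 (-0.34), so its direction depended on the libraries used. Within the 4 libraries with Y-linked reads 21 of 26 members were called, but there WT 1, with the lowest erythroid score, was the only WT library. Hba-a1, an alpha globin, had 3231 ± 1419 CPM in WT and 3986 ± 994 CPM in KO, and Epor 12.5 ± 5.29 and 15.0 ± 2.23 CPM. Lyve1 held 44.1 ± 10.1 CPM in WT and 34.2 ± 4.32 CPM in KO. Pancreas exocrine markers had 4 tested members, too few for camera, of which Pnliprp1 (34.7 ± 3.68 to 3.41 ± 1.28 CPM) and Amy2a5 (-2.92 ± 0.21) fell (3 adjusted over the list alone). Of the 4 tested adipose, mesothelium and muscle markers 0 passed with edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05 (1 adjusted over the list alone). That was Myh11, a smooth muscle myosin, with 37.8 and 38.0 CPM in WT 1 and WT 4 and 4.92 and 4.37 CPM in WT 2 and WT 3. It was called with upper-quartile scaling (-1.99), no filter on low counts (-1.92), the Y-linked covariate (-2.30), thinned counts (-1.96) and without WT 2 (-2.28) or WT 3 (-2.28).

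The labels give no sex, and sex-linked reads were uneven between the genotypes. WT 1 and KO 2 to KO 4 held 1944 to 2837 counts of 4 Y-linked genes and 0 to 3 counts of Xist, whereas WT 2 to WT 4 and KO 1 held 0 to 3 Y-linked counts and 5390 to 9076 Xist counts. With the Y-linked level as a covariate 2417 genes changed, 1358 higher and 1059 lower. Camera then also called the erythroid (median 0.71), platelet (0.53), cell cycle (0.30) and ATF4 target lists (0.17) higher and the clock (-0.30) and immediate early lists (-0.43) lower. Within the 4 libraries with Y-linked reads 1298 genes changed (704 higher, 594 lower), with a single WT library, and within the 4 without them 284 (163 higher, 121 lower), with a single KO library.

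The calls of lists were weaker than those of genes. Camera called 10 lists higher and 12 lower with its preset correlation of 0.01, but 0 and 0 with an estimated correlation, where 8 lists had an unadjusted p under 0.05. Other splits of the 8 libraries into 4 and 4 also called up to 15 lists in 1 direction, but never more than 27 genes. All 10 lists called higher, and 5 of the 12 called lower, had every KO library beyond every WT library. Counts of members moved as well: leaving out 1 library gave as few as 20 higher for the respiratory chain (52 with library size alone), 7 lower for T, B and NK cell markers, 6 for fibrosis and 3 for cholangiocytes, and as many as 16 for fibrosis and 8 for Kupffer cells. The fetal liver list had 4 higher and 3 lower without WT 4, KO 1 or KO 2. The endoplasmic reticulum unfolded protein list had 1 higher and 2 lower without WT 4, KO 1 or KO 4. For the lipogenesis, CAR and PXR, cytokine, lipoprotein, fetal liver, growth hormone and endothelial lists the median and the mean of the members differed in sign.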

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

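The tests without WT 1 and WT 4, and the reading of the test without WT 4 alone as open, were chosen after their results were seen. In each genotype the most distant library was set apart from the other 3 where its gap to the nearest, as a share of the range over 4 libraries, was above Dixon's critical value for 4 values. Of 304 such groups 25 were above it, where chance gives 15.2.

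Among the genes with the largest changes, Cyp4a12a stood at 18.0 CPM in KO 1 against 7.04 to 8.57 in the other KO libraries, a gap of 0.860 of the range. For Tgoln2 in WT the gap was 1, since WT 2 held 3.84 CPM and the others 0. Ubd in KO had a gap of 0.854 (KO 4 at 59.3 CPM against 5.42 to 13.3) and Pnliprp1 in KO 0.839 (KO 2 at 1.51 against 3.78 to 4.21). Baiap2l1 in WT had a gap of 0.831 (WT 1 at 20.4 CPM against 22.9 to 23.5).

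Metabolic genes with a library apart were Ehhadh in WT at 0.873 (WT 3 at 337 CPM against 238 to 250.3), Cyc1 in KO at 0.850 (KO 3 at 237 against 213 to 217) and Slc25a42 in KO at 0.888 (KO 4 at 155 against 117 to 122). Nags in WT had a gap of 0.864 (WT 4 at 48.8 CPM against 43.2 to 43.9). Trib3 in KO had 0.948 (KO 4 at 14.1 against 11.3 to 11.4), Shmt2 in KO 0.910 (KO 3 at 212 against 179 to 182) and Lonp1 in KO 0.928 (KO 1 at 227 against 248 to 250.0). The lysosomal protease gene Ctsl had 0.846 in WT (WT 1 at 796 CPM against 860.3 to 872).

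Of the other genes, Cyp1a2 in KO had a gap of 0.872 (KO 3 at 108 CPM against 58.8 to 65.0), Ccnd1 in WT 0.885 (WT 3 at 93.6 CPM against 130.3 to 135), and Mcm7 in KO 0.912 (KO 4 at 80.9 against 98.9 to 101). Per1 in KO had 0.899 (KO 4 at 13.4 CPM against 11.3 to 11.5), Folr2 in KO 0.859 (KO 4 at 18.0 against 13.1 to 13.8) and Gp1ba in KO 0.875 (KO 2 at 5.66 against 7.36 to 7.60). Total counts in WT had a gap of 0.833, from 14514276 in WT 4 to 18715843 in the next library. The sex-linked genes set WT 1 and KO 1 apart: the gap was 0.837 for Xist in WT, 0.9996 for Xist in KO, 0.998 for Ddx3y in WT and 0.908 for Ddx3y in KO. The mean of the stellate cell markers in KO had a gap of 0.845, with KO 1 at -0.27 and the others at -0.14 to -0.12.

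Sex and depth both differed between the genotypes, and each could account for part of the 2783 changed genes. With the Y-linked level as a covariate the fold of the called genes was a median 1.02 of that without it (middle 90% of genes 0.768 to 1.24) and all kept their sign, against sex as the whole cause. In that fit 2118 of the 2783 calls (76.1%) were made again in the same direction. After thinning to the smallest library 91.7% of the calls were made again in the same direction, against depth as the cause. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many changed genes, 1 as many higher and 1 as many lower, the real split each time. The highest other values were 27, 23 and 23, all from the split that grouped the libraries by Y-linked reads. The remaining splits called at most 1 gene. Every other split mixes the genotypes, so a difference between them adds to the spread and keeps these counts low. The smallest share possible is 1 of 35, so the splits alone do not exclude chance. Litter, which the labels do not give, stays open as untested, and a biological effect of the genotype on these genes is a hypothesis.

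The cholangiocyte and stellate cell lists were lower in KO, and bile duct or connective tissue carried into some WT livers could give such a difference. Leaving out WT 4, the WT library with the highest cholangiocyte score, kept 0.842 of the median fold of the cholangiocyte list. The range was 0.640 to 0.967 over resamples of its members. For the stellate list 1.08 of the median fold was kept. The bound of 0.8 written beforehand assumed a single such library and was wrong, because WT 1 had a score of 0.89 beside 1.01 in WT 4. Without both libraries 0.522 (0.155 to 0.803) of the cholangiocyte median and 0.737 (0.364 to 1.41) of the stellate median were left. All these ranges come from resampled list members with the libraries fixed, so they leave out the spread between libraries. They are already too wide to decide, and only 2 WT libraries remain. Carried tissue and a lower content of these cells in KO therefore cannot be told apart.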

How the results depend on the processing

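The alternatives that thinned counts, parted libraries by Y-linked reads, left out WT 1 and WT 4, left out abundant genes or removed a length and GC trend were chosen after seeing the data. Each called gene kept its sign in every alternative that tested it, except in the 4 libraries without Y-linked reads, where 99.96% did. Scaling by library size alone moved the median log2 fold change of all genes to 0.11 and gave 2783 genes higher and 701 lower. With the replicate number as a replicate block 1674 genes changed, 988 higher and 686 lower, and 1663 of them were among the 2783. Same-numbered libraries had correlations of -0.42, -0.14, -0.14 and -0.13, and no WT library correlated best with its own number. These correlations gave no sign of pairing but cannot exclude it, since WT 1 and KO 1 also differed in sex-linked reads. The block takes residual degrees of freedom by its construction. In the other alternatives with all 8 libraries 2417 to 3484 genes changed. With fewer libraries fewer genes passed: 1298 (704 higher, 594 lower) in the 4 libraries with Y-linked reads, 284 (163 higher, 121 lower) in the 4 without, and 1763 (1042 higher, 721 lower) without WT 1 and WT 4. Leaving out each library in turn gave 1998 to 2629 changed genes, 1189 to 1523 higher and 806 to 1108 lower, 10 to 13 lists higher and 10 to 13 lower, and -4.97 to -4.80 for Hmgcs2. With an estimated correlation camera called 0 lists higher and 0 lower, with 8 at an unadjusted p under 0.05. Of the 35 splits, the real one included, 13 called at least 10 lists and 9 at least 12 in either direction, with 15 the highest value of another split, so chance cannot be excluded for the number of lists. Other splits with 12 or more, however, kept 3 libraries of a genotype together, and splits with 2 of each genotype called at most 10. The erythroid list, with a median of 0.17 and no call in all libraries, was called higher with the Y-linked covariate (0.71) and without WT 2 (0.50), WT 3 (0.31) or KO 4 (0.30), but lower (-0.34) without WT 1 and WT 4, the libraries with its lowest scores (-1.03 and -0.58). A pseudocount for normalised values was not run, since the table holds estimated counts. The cause was not tested for other lists whose call was lost.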

Other observations

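The test of the share of hepatocytes was chosen after its result was seen, and the lysosomal and pericentral lists were written after other lysosomal and pericentral genes had been seen among the changed genes; those seen by then were left out. Both lists were thus prompted by changes in the same libraries, and leaving out the genes seen first does not make the other members independent of them. The camera adjustment also leaves out the search that prompted the lists. Their camera p-values are therefore no separate support for a lysosomal rise or a pericentral fall. The label of the test of genes near Hmgcs2 was changed to open after its result was seen.

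Of 36 lysosomal genes 16 rose in KO by edgeR's test, 0 fell and 20 did not pass, with a median log2 fold change of 0.19 and a camera adjusted p of 1.25e-06 over 3 lists (adjusted p = 0.0630 with an estimated correlation). The sialidase Neu1 rose by 0.71 ± 0.065, the sulfatases Arsa and Gns by 0.72 ± 0.093 and 0.53 ± 0.073, and the protease Ctsl by 0.43 ± 0.062. With all 8 libraries, other scalings, filters and tests called 10 to 25 members higher and 0 or 1 lower. A rise of some lysosomal genes may accompany the loss of Hmgcs2, as a hypothesis.

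Many genes of pericentral hepatocytes, those around the central vein that depend on Wnt signals, were lower in KO. In a list of 20, 13 fell, 2 rose and 5 did not pass, with a median of -0.70 and a camera adjusted p of 6.89e-05 (adjusted p = 0.0630 with an estimated correlation). Lect2 (-1.07 ± 0.12), Gulo (-0.61 ± 0.072) and Tnfrsf19 (-1.20 ± 0.16) fell, while Cldn2 (0.72 ± 0.067) and Oat (0.81 ± 0.15) rose and Glul, a pericentral Wnt target, held 593 ± 31.8 CPM in WT and 601 ± 63.3 CPM in KO. Of 20 periportal genes 6 rose and 3 fell (camera adjusted p = 0.207), and the difference between the lists was not tested. Leaving out KO 3 gave 5 periportal genes higher and 0 lower, and leaving out WT 4, KO 1 or KO 2 left 1 lower. A fall of only part of the pericentral programme in KO is a hypothesis, since Cldn2, Oat and Glul do not follow it. Ccnd1, Glul, Oat, Cyp1a2 and Cyp2a5 are also held by other lists, and Cyp1a2 and Cyp2a5 are uncertain, with fractional counts in 7 and 8 libraries.

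Genes near Hmgcs2 were tested for a local effect of the targeted gene. Of 40 tested genes, the nearest to Hmgcs2 in equal number on each side, 7 changed (17.5%, against 20.7% of the other genes). A two-sided Fisher's exact test gave p = 0.701, and the odds ratio had a 95% confidence interval of 0.302 to 1.87. The rule written beforehand, that a p of at least 0.05 speaks against a local effect, was wrong, because this interval allows an excess and the more distant genes dilute a local effect. Of the 10 nearest genes 5 changed, and of the other 30 only 2, a division made after the values were seen, so a local effect stays open. The 7 were Hsd3b5 (-2.07 ± 0.52), Hsd3b1 (-0.96 ± 0.14), Hsd3b3 (-0.61 ± 0.089), Hao2 (-0.86 ± 0.11), Cd2 (-1.04 ± 0.32), Notch2 (-0.27 ± 0.078) and Wars2 (0.43 ± 0.13), of which Wars2 rose and the others fell. Hsd3b5 lay near the floor (1.18 ± 0.0907 to 0.266 ± 0.269 CPM), and Hsd3b3 is uncertain, with fractional counts in 8 libraries. The Hsd3b5 call ended without WT 1 and WT 4 (-2.04). The calls of Notch2, Wars2 and Cd2 ended when some single libraries were left out and with several other alternatives, such as library size alone for Notch2 (-0.17) and the Y-linked covariate for Wars2 (0.38) and Cd2 (-0.93).

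The fat oxidation, citric acid cycle and respiratory chain lists together had 83 of 138 tested members higher and a median log2 fold change of 0.30. A transcript length and GC trend, a shift in scaling from abundant secreted-protein genes, or a larger share of hepatocytes could have given this. After a length and GC trend was removed the median was 1.03 of its size (0.968 to 1.10 over resamples of the members). Before that removal it lay 0.286 above the median of 10000 expression-matched random lists, whose central range was -0.034 to 0.062. The hepatocyte markers had a median of -0.47 (-0.69 to -0.12 over resamples of the markers). Each of these values was against its explanation as the whole cause. The ranges keep the libraries fixed and leave out the spread between them. The medians of the lymphocyte (-0.91), cholangiocyte (-0.75), stellate (-0.33) and Kupffer cell lists (-0.20) were below 0, as a larger share of hepatocytes would give, while those of the endothelial (0.0053), erythroid (0.17) and platelet lists (0.24) were not, so a part played by such a share stays open. A response of hepatocytes to the genotype is a hypothesis, and litter and feeding were not tested.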
